A study of Rattus norvegicus with 120 samples.

How the data were processed

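Poly-A RNA of frozen kidney and heart of ZSF1 rats, which received the compounds in chow, was made into stranded mRNA libraries, 120 in all. Replicates 1 to 5 of each of the 12 groups of 10 were on plate 1 and 6 to 10 on plate 2, per the labels, and 43 libraries had a repeat run. Labels call every renal sample kidney, while the series text speaks of whole kidney and cortex, and which kidney and heart came from one rat was not used here. The deposited count tables hold expected counts, which are estimated counts per gene from one run, unnormalized, and 6.61% of values are not whole. The deposited comparison tables hold signal, which is counts scaled by the authors for each library, beside log2 fold changes with standard errors, p-values and adjusted p-values from the authors' test. The submitters' processing notes name STAR 2.7.3a, Salmon 1.5.2, FastQC 0.11.9, Picard, MultiQC 1.11, DESeq2 1.34.0 and build mRatBN7.2, and their parameters are not given in the sources used here. The authors' scaled counts were proportional to the sum of both runs in 56 of 56 cases, so runs were summed. Of the count columns 163 were used, and 82 that match no sample of the series were not used here.

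Kidney libraries held a median of 10.1 M counts (M, 1000000) and up to 54.9 M. BT2 replicate 2 had 22773 counts and study B vehicle replicate 8 0.776 M, and the other kidney libraries had at least 4.6 M. Heart libraries held 6.74 to 23.6 M, with a median of 12.2 M. Mitochondrial transcripts took group medians of 13.6% to 17.0% in kidney and 38.7% to 46.6% in heart. All libraries entered the tests, but those under 1000000 counts were left out of means and SDs. Genes were named by the deposited symbols, with 8 taken from the deposited description.

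Summed counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16, using filterByExpr, TMM normalization, a trended dispersion without a tagwise one and the quasi-likelihood F test with the plate as covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Each comparison used its own pair of groups. Differences of effects between organs, or of BT2 with and without empagliflozin, were tested as interactions. Lists of genes (34, with 555 of 583 genes found by symbol and 28 not analysed here) were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. Effects were related by Pearson correlation over genes, beside simulated unchanged groups where vehicle libraries were shared, and shared calls were set beside the number for independent lists. CPM values use TMM factors of the libraries compared.

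Tests, lists and most alternatives were chosen before the data were examined, and so was the rule for naming genes. Named genes are the 6 highest and 6 lowest called genes with a symbol and at least 5 CPM in a group, up to 4 called members of each list with the smallest adjusted p, and Bckdk, Ppm1k, Bckdha, Bckdhb, Dbt, Bcat2 and Lepr, with Slc5a2, Slc5a1, Havcr1 and Lcn2 in kidney and Nppa, Nppb, Myh7, Myh6 and Pdk4 in heart. Only those that carry the text are printed, and some genes are not reported here. The pipeline was tested on simulated data at these depths, where 61.2% to 82.1% of genes with a 1.5-fold change, 86.6% to 97.0% with a 2-fold and 98.5% to 100% with a 4-fold change were recovered, and 2.30% to 6.77% of calls were false. Alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors, no low-count filter, no plate term, the replicate number as a block, each plate alone, all 6 groups of an organ in one fit, the original or repeat run alone and a term for a repeat run. Chosen after seeing the data were leaving out the 3 kidney libraries absent from the authors' tables, heart study A vehicle replicate 10, and 6 kidney and 11 heart libraries with another tissue's transcripts (kidney over 100 times the median of Actc1 or Alb, heart over 5 times that of Myl7 or 100 times that of Myh4).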

Results

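RNA from kidney and heart of 30-week-old ZSF1 rats was sequenced in 120 libraries, 60 per organ. ZSF1 obese rats, which lack a working leptin receptor, were set against lean ones. BT2 inhibits the kinase BDK (gene Bckdk), which switches off the branched-chain ketoacid dehydrogenase that degrades leucine, isoleucine and valine. Empagliflozin inhibits SGLT2 (gene Slc5a2), which takes up glucose in the proximal tubule. Study A held lean vehicle, obese vehicle and obese BT2 groups, and study B held obese vehicle, obese empagliflozin and obese combination groups. Each of the 12 groups had 10 libraries, one rat each per the series text. Log2 fold changes of leading genes are given ± SE, and numbers of libraries higher or lower are against the other group's median. Lists of genes were tested with camera, and a count in parentheses after a list's count is the one adjusted over the list alone, given where it differs.

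Some libraries carried transcripts of another tissue. Kidney lean replicate 8 held Actc1, cardiac actin, at 2510 CPM (counts per 1000000 counts) against a kidney median of 1.24 CPM. Kidney combination replicate 7 and BT2 replicate 2 held Actc1 at 264 and 185 CPM. Myh4, the fast myosin of skeletal muscle, stood at 10800 CPM in lean replicate 8 and 45500 CPM in BT2 replicate 2, which held only 22773 counts. Alb, the albumin of liver, reached 834, 266 and 95.9 CPM in kidney combination replicates 5, 4 and 1. In heart, Myl7, the atrial light chain of myosin, had a median of 137 CPM and exceeded 5 times that in 9 libraries, led by study B vehicle replicate 7 at 2870 CPM and empagliflozin replicate 6 at 2860 CPM. Myh4 reached 976 CPM in heart combination replicate 9 and 802 CPM in heart BT2 replicate 4. Counts of called genes are therefore also given without these 6 kidney and 11 heart libraries, a setting chosen after seeing the data. Heart lean replicate 8, with the kidney gene Umod at 62.3 against a median of 0.247 CPM, stays in them.

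Obese against lean kidneys show what the disease changed without drug. The injury marker Havcr1 (ENSRNOG00000007243), the KIM-1 protein shed by damaged proximal tubules, rose in 10 of 10 obese kidneys to 262 ± 94.1 against 22.7 ± 47.3 CPM (mean ± SD, n = 10 and 10). Lcn2 (ENSRNOG00000013973), or NGAL, rose to 32.8 ± 9.04 against 4.04 ± 4.80 CPM (n = 10 and 10). Ppm1k (ENSRNOG00000006893), the phosphatase that switches the branched-chain dehydrogenase on, fell to 40.4 ± 6.72 against 93.7 ± 15.3 CPM and was lower in 10 of 10 obese kidneys.

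The highest log2 fold changes belonged to Havcr1 at 3.76 ± 0.65, Il24 at 3.49 ± 0.67, A2m at 3.41 ± 0.49, Il19 at 3.37 ± 0.59, Atp12a at 3.04 ± 0.27 and Lcn2 at 2.98 ± 0.37. The lowest were Cyp8b1 at -3.94 ± 0.30, Serpinb12 at -3.82 ± 0.25, Klk1c4 at -2.89 ± 0.29, Anxa13 at -2.80 ± 0.29, Cftr at -2.48 ± 0.24 and Tnni3k at -2.46 ± 0.87. Klk1c4 can share reads with near-identical kallikreins and is uncertain. Without lean replicate 8, the library with muscle transcripts, Havcr1 stood at 5.14 ± 0.31, Il24 at 6.17 ± 0.50, A2m at 4.85 ± 0.28, Il19 at 5.87 ± 0.38 and Lcn2 at 3.70 ± 0.20. Tnni3k, a cardiac kinase, then lost its call at -0.72 ± 0.35 (adjusted p = 0.118) by edgeR's quasi-likelihood test.

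Among genes of branched-chain amino acid catabolism, 21 of 26 fell and 1 rose (23 and 1 adjusted over the list alone), with Ppm1k at -1.21, Bcat2 at -0.71, Ivd at -0.58 and Bckdhb at -0.42. Their median was -0.43 (camera adjusted p = 7.16e-13, adjusted p = 0.0792 with an estimated correlation). Bckdha and Dbt, encoding dehydrogenase subunits, fell to -0.47 and -0.45, and the kinase gene Bckdk to -0.22 (edgeR adjusted p = 0.0106). Of the respiratory chain genes 22 of 26 fell (26), such as Sdha at -0.35 and Atp5f1c at -0.39. Their median was -0.34 (camera adjusted p = 1.6e-08, adjusted p = 0.265 with an estimated correlation). In fatty acid oxidation 8 of 20 fell and 1 rose (9 and 1), with Acadm at -0.50. Their median was -0.24 (camera adjusted p = 0.0197, adjusted p = 0.61 with an estimated correlation). Without lean replicate 8 the fatty acid oxidation list did not pass (camera adjusted p = 0.196). Ketone genes went mostly down, as 6 of 9 fell and 1 rose (7 and 1), with the ketone-using enzymes Oxct1 at -0.87 and Bdh1 at -0.60. Their median was -0.39 (camera adjusted p = 0.00157, adjusted p = 0.113 with an estimated correlation). In lipogenesis 9 of 17 fell and 1 rose (10 and 1), with Me1 at -0.91 and Scd2 at -0.88. Their median was -0.38 (camera adjusted p = 0.00122, adjusted p = 0.113 with an estimated correlation). Glucose response genes went up, as 5 of 10 rose and 0 fell (5 and 1), with Klf10 at 1.01. Their median was 0.29 (camera adjusted p = 0.0288, adjusted p = 0.113 with an estimated correlation).

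Of the tubule injury genes 26 of 28 rose and 1 fell (27 and 1), including Cd44 at 1.56 and C3 at 1.38. Their median was 1.35 (camera adjusted p = 5.91e-18, adjusted p = 0.113 with an estimated correlation). In the extracellular matrix list 25 of 32 rose (26), with Tnc at 1.65 and Timp1 at 1.81. Their median was 0.77 (camera adjusted p = 9.05e-15, adjusted p = 0.114 with an estimated correlation). Among myeloid markers 18 of 21 rose (19), with Laptm5 at 1.27. Their median was 1.0 (camera adjusted p = 1.96e-12, adjusted p = 0.113 with an estimated correlation). Among lymphoid markers 10 of 13 rose, with Cd3e at 1.41. Their median was 1.0 (camera adjusted p = 6.4e-06, adjusted p = 0.113 with an estimated correlation). Interferon response genes included Cxcl10 at 1.16 and Psmb8 at 1.06, and 19 of 26 rose and 1 fell (22 and 1). Their median was 0.46 (camera adjusted p = 3.28e-07, adjusted p = 0.198 with an estimated correlation). Among cell cycle genes 19 of 22 rose, with Top2a at 1.85. Their median was 1.46 (camera adjusted p = 5.54e-13, adjusted p = 0.113 with an estimated correlation). Among immediate-early genes 12 of 14 rose (13), with Egr2 at 2.52. Their median was 0.79 (camera adjusted p = 5.62e-07, adjusted p = 0.171 with an estimated correlation).

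Among proximal tubule markers 11 of 22 fell (14), with Slc7a13 at -1.16 and Miox at -1.0. Their median was -0.43 (camera adjusted p = 1.34e-05, adjusted p = 0.3 with an estimated correlation). Slc5a2, the target of empagliflozin, stood at -0.45 ± 0.17 with edgeR adjusted p = 0.0455. Among intercalated cell markers 9 of 10 fell, with Slc26a4 at -0.78. Their median was -0.39 (camera adjusted p = 0.000425, adjusted p = 0.311 with an estimated correlation). Endothelial markers included Vwf at -1.06, and 5 of 12 fell and 1 rose. Their median was -0.18 (camera adjusted p = 0.0322, adjusted p = 0.311 with an estimated correlation). The remaining 14 lists did not pass camera (adjusted p = 0.0656 to 0.957). In them the higher and lower genes were 5 and 6 of 20 for PPARα target, 1 and 2 of 8 (1 and 3) for gluconeogenesis, 5 and 1 of 18 (5 and 2) for cholesterol synthesis, 7 and 4 of 17 (8 and 5) for ATF4 stress, 2 and 5 of 14 (2 and 6) for NRF2 target, 2 and 2 of 6 for AHR target, 1 and 3 of 16 for clock, 0 and 0 of 9 for adipocyte, 0 and 1 of 5 for erythroid, 1 and 5 of 14 (1 and 6) for angiotensin and aldosterone, 3 and 4 of 15 for podocyte, 4 and 5 of 12 for thick ascending limb, 0 and 2 of 8 for distal convoluted tubule and 0 and 0 of 10 for principal cell. Median, mean and test differed in sign for erythroid (median 0.05, mean 0.08, test down). Adrenal markers had fewer than 3 measured members. Lepr, the mutated receptor, stood at -1.14 ± 0.22, and Slc5a1 did not pass, with edgeR adjusted p = 0.172.

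By edgeR's quasi-likelihood test 4559 of 14230 genes differed between obese and lean kidneys, 2398 higher and 2161 lower in obese. Without lean replicate 8 the count was 5423 (2792 higher and 2631 lower), and plate 2 alone gave 976. The authors' deposited table, which leaves out lean replicate 8, lists 6036 genes at its adjusted p threshold.

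BT2 against vehicle in obese kidneys asks what BDK inhibition changes by itself. Scd2 (ENSRNOG00000046005), a fatty acid desaturase, rose to 489 ± 104 against 90.2 ± 16.7 CPM (n = 9 and 10), and Srebf1 (ENSRNOG00000003463), the regulator of fat synthesis, to 110.4 ± 26.2 against 30.3 ± 6.90 CPM, each in 9 of 9 libraries. Among the genes of the BT2 target pathway only Bcat2, the first transaminase, was called over all genes, at 0.53 ± 0.10 with edgeR adjusted p = 0.00389 and higher in 8 of 9 libraries.

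The genes that rose most were Slc22a13 at 2.58 ± 0.22, Creb3l3 at 2.44 ± 0.20, Scd2 at 2.40 ± 0.18, Acaa1b at 2.05 ± 0.18, Srebf1 at 1.86 ± 0.15 and Ehhadh at 1.54 ± 0.20. The genes that fell most were Cyp2c11 at -5.76 ± 0.30, Angptl7 at -5.01 ± 0.35, Slco1a1 at -3.74 ± 0.15, Cyp2c24 at -2.74 ± 0.20, Sult4a1 at -2.13 ± 0.19 and Slc16a14 at -1.65 ± 0.23, where the Cyp2c family can share reads and is uncertain. In lipogenesis 7 of 17 rose (8 adjusted over the list alone), with Fads1 at 0.64 and Fads2 at 0.80. Their median was 0.22 (camera adjusted p = 3.12e-07, adjusted p = 0.0244 with an estimated correlation). Of the cholesterol synthesis genes 5 of 19 rose (10), such as Insig1 at 0.70. Their median was 0.24 (camera adjusted p = 0.000986, adjusted p = 0.484 with an estimated correlation). Among PPARα targets 6 of 20 rose and 2 fell (11 and 3). Their median was 0.32 (camera adjusted p = 0.00702, adjusted p = 0.633 with an estimated correlation). Fatty acid oxidation had Acsl1 at 1.0 and Eci1 at 0.71, and 3 of 20 rose (4). Their median was 0.16 (camera adjusted p = 0.000981, adjusted p = 0.603 with an estimated correlation). Among cell cycle genes 14 of 22 fell (19), with Mki67 at -1.13. Their median was -0.72 (camera adjusted p = 1.11e-12, 0.0738 with an estimated correlation). Interferon response genes included Oas2 at -1.34, and 4 of 26 fell (13). Their median was -0.35 (camera adjusted p = 5.37e-08, 0.198 with an estimated correlation). Among myeloid markers 3 of 21 fell (12), with Itgam at -0.70. Their median was -0.30 (camera adjusted p = 3.12e-07, 0.165 with an estimated correlation).

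Of the intercalated cell markers 7 of 10 rose (9), with Aqp6 at 0.51. Their median was 0.50 (camera adjusted p = 6.96e-07, 0.165 with an estimated correlation). Among principal cell markers 4 of 10 rose (8), with Aqp4 at 0.63. Their median was 0.50 (camera adjusted p = 1.48e-06, 0.0738 with an estimated correlation). The proximal tubule genes Gatm at -1.33 and Slc5a1 at -0.60 and the glucose-handling genes Slc2a2 at -0.80 and Fbp1 at -0.61 fell. In the lists shifted down with them the higher and lower genes were 1 and 3 of 22 (1 and 8) for proximal tubule, 0 and 3 of 8 (0 and 5) for gluconeogenesis, 0 and 3 of 10 (0 and 5) for glucose response and 0 and 1 of 26 for oxidative phosphorylation (camera adjusted p = 0.00124 to 0.0238, adjusted p = 0.165 to 0.639 with an estimated correlation). Podocyte markers shifted up with 0 and 0 of 15 (3 and 0) (camera adjusted p = 0.0251, 0.63 with an estimated correlation). The other lists did not pass camera (adjusted p = 0.0682 to 0.986), branched-chain amino acid catabolism at 0.986 with 1 of 26 rose (3). Ppm1k stood at 0.24 ± 0.12, Bckdk at -0.07 ± 0.07, Havcr1 at -0.18 ± 0.20, Lcn2 at -0.23 ± 0.16 and Slc5a2 at -0.25 ± 0.18, with edgeR adjusted p = 0.203, 0.511, 0.592, 0.37 and 0.401. In all, edgeR called 812 of 14311 genes, 324 higher and 488 lower. Without BT2 replicate 2, the library of 22773 counts, the count was 1186 (541 higher and 645 lower), and Bckdha, at 0.35 ± 0.11 before, passed at 0.36 ± 0.11 (adjusted p = 0.0485). The plates alone gave 113 and 70.

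Empagliflozin against the study B vehicle asks what SGLT2 inhibition changes in the obese kidney. Cyp24a1 (ENSRNOG00000013062), the enzyme that inactivates vitamin D, rose to 427 ± 125 against 115 ± 32.5 CPM (n = 10 and 9) and was higher in 10 of 10 libraries. Ace (ENSRNOG00000062101), which makes angiotensin II, rose to 44.6 ± 10.2 against 19.3 ± 3.05 CPM, in 10 of 10 libraries. Vdr, the vitamin D receptor, rose to 46.9 ± 25.4 against 21.2 ± 4.86 CPM, while the phosphate transporter Slc34a3 fell to 6.77 ± 3.96 against 13.0 ± 2.89 CPM. Slc5a2 itself was not called, at 0.12 ± 0.24 with edgeR adjusted p = 0.837. Havcr1 and Lcn2 were not called either, at 0.12 ± 0.13 and 0.18 ± 0.20 with edgeR adjusted p = 0.648 and 0.648.

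The highest called genes were Cyp24a1 at 1.95 ± 0.18, Apoc2 at 1.5 ± 0.27, Ceacam20 at 1.19 ± 0.18, Ace at 1.18 ± 0.12, Ptgs2 at 1.16 ± 0.25 and Vdr at 1.15 ± 0.21, and the lowest Mpped1 at -1.08 ± 0.22, Slc34a3 at -1.03 ± 0.24, S100b at -0.91 ± 0.18, Mypn at -0.80 ± 0.16, Apoc3 at -0.78 ± 0.14 and Sdsl at -0.75 ± 0.17. Without study B vehicle replicate 8, the shallow library, Slc34a3 and Sdsl lost their calls at -0.99 ± 0.23 (adjusted p = 0.0534) and -0.73 ± 0.17 (adjusted p = 0.0506) by edgeR. Among proximal tubule genes 3 of 22 fell and 0 rose (4 and 2 adjusted over the list alone), with Miox at -0.67 and Slc22a6 at -0.57, and this list did not pass (camera adjusted p = 0.238). Single called genes that fell were Fbp1 at -0.52 and Pc at -0.39, of glucose making, Cox5b at -0.34, of respiration, Acaa1a at -0.30, of peroxisomal oxidation, and Atf4 at -0.22, of the amino acid stress response. In their lists and in fatty acid oxidation the higher and lower genes were 0 and 2 of 8 (0 and 5) for gluconeogenesis, 0 and 1 of 26 (0 and 9) for oxidative phosphorylation, 0 and 1 of 19 (0 and 6) for PPARα target, 0 and 2 of 19 (0 and 3) for ATF4 stress and 0 and 0 of 20 (0 and 10) for fatty acid oxidation (camera adjusted p = 2.46e-06 to 0.0241, adjusted p = 0.244 to 0.442 with an estimated correlation). Acaa1a and Atf4 lost their calls without vehicle replicate 8, at -0.29 ± 0.07 (adjusted p = 0.0593) and -0.21 ± 0.05 (adjusted p = 0.0602) by edgeR.

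Some lists shifted without a gene called over all genes. In those shifted up the higher and lower genes adjusted over the list alone were 3 and 0 of 8 for distal convoluted tubule, 1 and 0 of 15 for podocyte and 0 and 0 of 22 for cell cycle (camera adjusted p = 0.00165 to 0.00211, adjusted p = 0.357 to 0.52 with an estimated correlation). Lymphoid markers passed upward (camera adjusted p = 0.0249, adjusted p = 0.812 with an estimated correlation), but not without empagliflozin replicate 1 (camera adjusted p = 0.441), which held the antibody gene Jchain at 410 against a kidney median of 4.05 CPM, and angiotensin and intercalated cell lists then did (adjusted p = 0.0312 and 0.0302). Erythroid and glucose response genes shifted down, with 0 and 3 of 4 for erythroid and 0 and 2 of 10 for glucose response in the same way (camera adjusted p = 0.00174 and 0.00487, adjusted p = 0.357 and 0.244 with an estimated correlation). The remaining lists did not pass (camera adjusted p = 0.0788 to 0.902), among them branched-chain amino acid catabolism at adjusted p = 0.473 with none of 26 genes called. Bckdk, Ppm1k and Bckdha stood at -0.10 ± 0.06, 0.37 ± 0.22 and -0.21 ± 0.09, with edgeR adjusted p = 0.347, 0.383 and 0.186. By edgeR 149 of 14059 genes were called, 66 higher and 83 lower, and 92 (45 higher and 47 lower) without vehicle replicate 8. The count was 25 without the plate term, 623 by DESeq2, and 2 and 21 within each plate.

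Combination treatment against the study B vehicle changed the obese kidney much more widely than empagliflozin alone by gene count. Ppm1k, which obesity lowered in study A, rose to 54.7 ± 14.6 against 14.0 ± 4.00 CPM (n = 10 and 9). It was higher in 10 of 10 libraries. Scd2 rose to 929 ± 258 against 82.8 ± 20.4 CPM and Ehhadh (ENSRNOG00000001770), a peroxisomal oxidation enzyme, to 415 ± 58.3 against 89.6 ± 16.7 CPM. Havcr1 and Lcn2 fell, at -0.61 ± 0.15 and -1.02 ± 0.16 with edgeR adjusted p = 0.00237 and 3.84e-05. Slc5a2, the target of empagliflozin, fell to 40.5 ± 13.1 against 84.0 ± 17.5 CPM, and Slc34a1, the main renal phosphate transporter, to 618 ± 94.8 against 1571 ± 152 CPM.

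The highest called genes were Actc1 at 4.38 ± 1.26, Scd2 at 3.52 ± 0.14, Slc22a13 at 3.27 ± 0.25, Myl2 at 3.10 ± 1.04, Chrna2 at 2.86 ± 0.19 and Gjd2 at 2.59 ± 0.26, and the lowest Myh4 at -3.01 ± 0.74, Cyp2c11 at -2.98 ± 0.74, Slco1a1 at -2.58 ± 0.26, Cyp2c24 at -2.29 ± 0.22, Slc34a3 at -2.22 ± 0.23 and Tnnt3 at -1.99 ± 0.45. Actc1 and Myl2 are muscle genes and stood highest in combination replicate 7, the library noted above. Without the combination libraries with other-tissue transcripts, they lost their calls at 0.67 ± 0.33 (adjusted p = 0.141) and 0.49 ± 0.34 (adjusted p = 0.324) by edgeR, and Cyp2c11 moved to -5.56 ± 0.76. Of the branched-chain amino acid genes 19 of 26 rose and 1 fell (19 and 1 adjusted over the list alone), with Ppm1k at 2.00, Bcat2 at 0.79, Dbt at 0.51 and Bckdha at 0.39. Their median was 0.29 (camera adjusted p = 3.8e-07, adjusted p = 0.229 with an estimated correlation). Bckdk, the target of BT2, was not called, at 0.10 ± 0.05 with edgeR adjusted p = 0.166. In lipogenesis 12 of 17 rose, with Srebf1 at 2.19 and Fads2 at 1.91. Their median was 0.56 (camera adjusted p = 1.64e-09, adjusted p = 0.0423 with an estimated correlation). PPARα targets included Ehhadh at 2.24 and Acaa1b at 1.90, and 11 of 19 rose and 4 fell (12 and 4). Their median was 0.44 (camera adjusted p = 2.42e-06, adjusted p = 0.154 with an estimated correlation). Of the fatty acid oxidation genes 13 of 20 rose (15), such as Ech1 at 0.85. Their median was 0.27 (camera adjusted p = 1.63e-07, adjusted p = 0.163 with an estimated correlation). Cholesterol synthesis genes such as Insig1 at 1.02 and the NRF2 targets Osgin1 at 1.45 and Gclm at 1.1 rose too, with 9 and 0 of 19 (11 and 1) for cholesterol synthesis and 7 and 1 of 14 for NRF2 target (camera adjusted p = 0.000668 to 0.0223, adjusted p = 0.136 to 0.299 with an estimated correlation).

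Among extracellular matrix genes 23 of 30 fell, with Timp1 at -1.15 and Col6a3 at -1.1. Their median was -0.67 (camera adjusted p = 8.9e-09, adjusted p = 0.229 with an estimated correlation). Of the tubule injury genes 19 of 28 fell and 2 rose (20 and 2), with Clu at -1.32 and Anxa2 at -0.68 against Cryab at 1.33. Their median was -0.57 (camera adjusted p = 3.8e-07, adjusted p = 0.163 with an estimated correlation). Among myeloid markers 17 of 20 fell (18), with Cd74 at -1.06. Their median was -0.85 (camera adjusted p = 9.69e-11, adjusted p = 0.163 with an estimated correlation). For cell cycle genes 18 of 22 fell, with Top2a at -1.26. Their median was -1.06 (camera adjusted p = 1.56e-08, adjusted p = 0.136 with an estimated correlation). The interferon gene Psmb8 at -1.0, the lymphocyte gene Cd6 at -1.02 and the immediate-early gene Egr2 at -1.79 fell as well, with 1 and 17 of 26 (1 and 20) for interferon response, 0 and 7 of 14 (0 and 8) for lymphoid and 1 and 6 of 14 for immediate-early (camera adjusted p = 1.18e-08 to 0.00598, adjusted p = 0.163 to 0.277 with an estimated correlation).

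Among intercalated cell markers 10 of 10 rose, with Slc4a9 at 1.18 and Aqp6 at 0.81. Their median was 0.70 (camera adjusted p = 8.8e-08, adjusted p = 0.136 with an estimated correlation). The distal convoluted tubule gene Emx1 at 0.95, the sodium channel subunit Scnn1g at 0.65, Ace at 1.03 and the clock genes Tef at 1.01 and Per3 at 1.06 rose too. In their lists the higher and lower genes were 4 and 0 of 8 (7 and 0) for distal convoluted tubule, 5 and 0 of 10 (6 and 1) for principal cell, 7 and 2 of 14 for angiotensin and aldosterone and 7 and 2 of 16 (8 and 2) for clock (camera adjusted p = 0.00444 to 0.0415, adjusted p = 0.163 to 0.297 with an estimated correlation). In the ATF4 list 8 of 19 fell and 2 rose (11 and 2), with Slc3a2 at -0.45 against Stc2 at 2.28 (camera adjusted p = 0.00279, adjusted p = 0.13 with an estimated correlation). Gluconeogenesis had Pc at -0.50 and Slc2a2 at -0.64, and 4 of 8 fell (camera adjusted p = 0.0434, adjusted p = 0.297 with an estimated correlation). Proximal tubule markers split, as 9 of 22 fell and 7 rose, with Slc22a7 at 2.01 and Aqp1 at 1.0 against Slc34a1 at -1.35 (camera adjusted p = 0.6). The other lists did not pass either (camera adjusted p = 0.0594 to 0.803). By edgeR 4510 of 14037 genes were called, 2433 higher and 2077 lower. The count was 4488 without vehicle replicate 8 and 3651 (1985 higher and 1666 lower) without the other-tissue libraries, with Calb1, Aqp2 and Bckdhb among the calls lost. These moved from 0.68 ± 0.25, 0.43 ± 0.14 and 0.28 ± 0.08 to 0.61 ± 0.29 (adjusted p = 0.135), 0.35 ± 0.17 (adjusted p = 0.131) and 0.27 ± 0.10 (adjusted p = 0.0605) by edgeR.

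Combination against empagliflozin alone shows what adding BT2 changed. Slc22a13, a urate and nicotinate transporter, rose to 45.2 ± 17.2 against 3.44 ± 1.46 CPM (n = 10 and 10), Scd2 to 949 ± 261 against 125 ± 30.6 CPM and Ppm1k to 55.9 ± 14.7 against 18.2 ± 7.46 CPM. The highest called genes were Slc22a13 at 3.76, Scd2 at 2.92, Acaa1b at 2.58, Chrna2 at 2.53, Ano2 at 2.26 and Thrsp at 2.17, and the lowest Slco1a1 at -3.61, Smpd3 at -3.32, Cyp2c24 at -3.30, Slpi at -3.02, Cyp2c11 at -2.73 and Jchain at -2.53. Without the libraries with other-tissue transcripts, Cyp2c11 moved to -5.44 ± 0.71, and Jchain, an antibody gene at 53.1 ± 131 CPM with empagliflozin, lost its call at -2.39 ± 1.28 (adjusted p = 0.204) by edgeR. Without empagliflozin replicate 1 Jchain stood at -1.04 ± 0.53 (adjusted p = 0.146) and Slpi at -2.23 ± 0.45 (adjusted p = 0.000777). Among branched-chain amino acid genes 19 of 26 rose and 1 fell (21 and 1 adjusted over the list alone), with Bckdha at 0.59 (camera adjusted p = 3.82e-09, adjusted p = 0.181 with an estimated correlation). Of the fatty acid oxidation genes 17 of 20 rose (18), such as Eci1 at 1.02 (camera adjusted p = 6.6e-13, adjusted p = 0.0945 with an estimated correlation). For oxidative phosphorylation 15 of 26 rose (17), with Ndufb8 at 0.42 (camera adjusted p = 2.93e-06, adjusted p = 0.33 with an estimated correlation). Among PPARα targets 13 of 19 rose and 2 fell (13 and 3), with Ehhadh at 2.12 (camera adjusted p = 1.56e-09, adjusted p = 0.0622 with an estimated correlation), and in lipogenesis 11 of 17 rose (13) (camera adjusted p = 1.9e-08, adjusted p = 0.0622 with an estimated correlation).

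Genes that the combination had lowered against vehicle fell against empagliflozin as well, among them Loxl2 at -1.02, Lcn2 at -1.20, Havcr1 at -0.73 and Cd74 at -1.25. In the lists shifted down the higher and lower genes were 0 and 25 of 30 (0 and 26) for extracellular matrix, 0 and 20 of 22 (0 and 21) for cell cycle, 1 and 18 of 28 (1 and 19) for tubule injury, 0 and 18 of 20 for myeloid, 0 and 21 of 26 (1 and 25) for interferon response, 0 and 10 of 14 (0 and 12) for lymphoid and 1 and 5 of 13 for immediate-early (camera adjusted p = 1.94e-12 to 0.00909, adjusted p = 0.0622 to 0.342 with an estimated correlation). Lists shifted up further were 11 and 0 of 19 for cholesterol synthesis, 6 and 1 of 14 (6 and 2) for NRF2 target, 8 and 0 of 16 (8 and 1) for clock, 3 and 0 of 4 (4 and 0) for erythroid and 4 and 0 of 10 (8 and 0) for intercalated cell (camera adjusted p = 0.000241 to 0.03, adjusted p = 0.181 to 0.3 with an estimated correlation). The remaining lists did not pass (camera adjusted p = 0.0623 to 0.801), but principal cell did without empagliflozin replicate 1 (adjusted p = 0.0317). Slc5a2 and Slc34a1 fell, at -1.14 ± 0.26 and -0.94 ± 0.10. By edgeR 4442 of 13992 genes were called, 2376 higher and 2066 lower, and 2950 (1544 higher and 1406 lower) without the other-tissue libraries. Bckdk, at 0.20 ± 0.05 before, then lost its call at 0.17 ± 0.07 (adjusted p = 0.0892).

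BT2's effect with minus without empagliflozin was called for 1167 of 14834 kidney genes by edgeR's interaction test, 665 higher and 502 lower, a count for which chance was not excluded. Each plate alone gave 122 and 8 genes. The arms come from different studies, so study and empagliflozin background are not separable here.

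Obese vehicle kidneys of study B against those of study A received no drug in either study. Slc5a12, a lactate transporter of the proximal tubule, fell to 20.3 ± 6.16 against 222 ± 118 CPM (n = 9 and 10). Nphs1, of the podocyte slit diaphragm, fell to 9.96 ± 4.88 against 40.1 ± 9.17 CPM, while Aqp2, the water channel of the collecting duct, rose to 477 ± 78.1 against 129.9 ± 60.4 CPM. Slc5a2 fell to 88.1 ± 18.8 against 225 ± 71.3 CPM. By edgeR 9442 of 14434 genes were called, 4895 higher and 4547 lower in study B and 9485 without vehicle replicate 8.

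The highest called genes were Metazoa_SRP at 3.65, Rn7sl1 at 3.46, Upk2 at 2.64, Upk3a at 2.48, Guca2b at 2.41 and Upk1a at 2.24, with Upk2, Upk3a and Upk1a from the lining of the urinary tract. The lowest were Actc1 at -4.02, Slc4a4 at -3.97, Tlr12 at -3.85, Myh7 at -3.85, Angptl7 at -3.83 and Mb at -3.72, with Actc1, Myh7 and Mb from muscle. Single libraries stood out, as study A vehicle replicate 4 held Actc1 at 102 CPM and study B vehicle replicate 1 Upk3a at 48.6 against a kidney median of 2.39 CPM. Among proximal tubule markers 14 of 22 fell and 2 rose (14 and 2 adjusted over the list alone), with Slc5a12 at -3.46 and Slc6a19 at -3.40. Their median was -0.45 (camera adjusted p = 0.00484, adjusted p = 0.647 with an estimated correlation). Among podocyte markers 12 of 15 fell and 1 rose, with Clic5 at -1.51. Their median was -0.80 (camera adjusted p = 0.000825, adjusted p = 0.647 with an estimated correlation). Distal convoluted tubule markers had Sgms2 at -1.32, and 7 of 8 fell and 1 rose. Their median was -1.27 (camera adjusted p = 0.00484, adjusted p = 0.647 with an estimated correlation). Among principal cell markers 7 of 10 rose, with Fxyd4 at 1.32. Their median was 0.74 (camera adjusted p = 0.00893, adjusted p = 0.647 with an estimated correlation). Of the tubule injury genes 16 of 28 rose and 3 fell, with Krt18 at 1.3 and Lcn2 at 1.41 against Itgb6 at -0.99, while Havcr1 was not called, at 0.12 ± 0.16 with edgeR adjusted p = 0.515. Their median was 0.59 (camera adjusted p = 0.0104, adjusted p = 0.758 with an estimated correlation).

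Single metabolic genes called lower in study B were Ppm1k at -1.58, Acsl1 at -1.07 and Pck1 at -1.84. In the lists shifted down the higher and lower genes were 3 and 12 of 26 for branched-chain amino acid, 2 and 13 of 20 for fatty acid oxidation, 4 and 12 of 20 for PPARα target, 1 and 7 of 9 for ketone metabolism and 1 and 6 of 8 (1 and 7) for gluconeogenesis (camera adjusted p = 0.0143 to 0.0393, adjusted p = 0.647 to 0.863 with an estimated correlation). The other lists had called genes in both directions and did not pass (camera adjusted p = 0.227 to 0.86). Median, mean and test differed in sign for NRF2 target (median -0.05, mean 0.12, test up).

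Treatment effects were compared with the effect of obesity over genes called between obese and lean kidneys. Genes that obesity raised, such as Havcr1 and Top2a, tended to fall with the combination, and those it lowered, such as Ppm1k and Scd2, tended to rise, with r = -0.663 (-0.622 and -0.597 with the effects taken from different plates). Of the genes raised by obesity 1079 fell with the combination, where 348 would be shared by independent lists, and of those lowered 994 rose against 367. These vehicle groups are separate and differ without drug, with 9442 genes called between them. For BT2 alone, which shares its vehicle with the obesity contrast, r = -0.248 (-0.145 and -0.223 from different plates). There simulated null data with the same shared vehicle gave r = -0.483 (covariance -0.0589 against -0.0113 simulated). The genes were chosen with that vehicle on both plates, which the simulation did not repeat, so the shared vehicle may explain r. Empagliflozin gave r = 0.0928 (-0.321 and 0.256 from different plates), so its sign depended on the plate. Empagliflozin and combination effects, over all genes measured in both, gave r = 0.251 (-0.0771 and 0.416 from different plates). Here simulated null data with the same shared vehicle gave r = 0.501 (covariance 0.0231 against 0.0179 simulated).

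**Figure D1:**
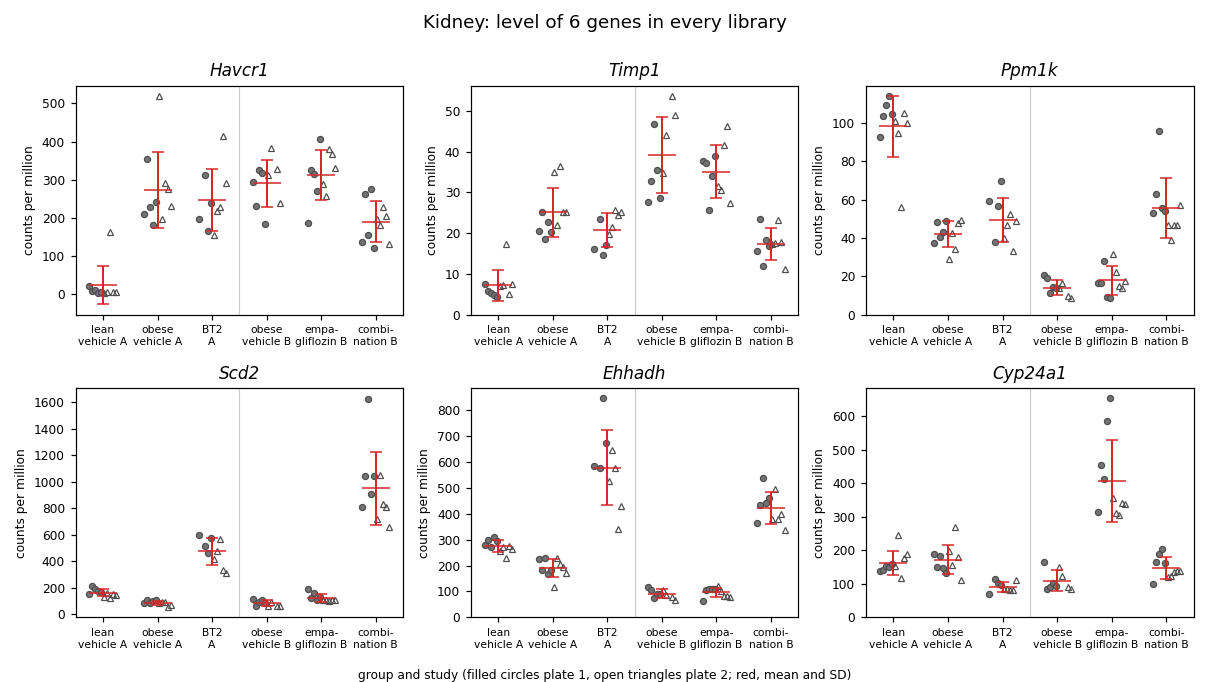
Levels in CPM of 6 kidney genes in every library with at least 1000000 counts, by group and study, with plate 1 as filled circles, plate 2 as open triangles and mean and SD in red. Havcr1 was high in obese groups and lower with the combination, where Scd2 and Ppm1k rose.

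Obese against lean hearts showed higher levels of some genes of fat use. Angptl4 (ENSRNOG00000007545), a lipase inhibitor induced by fatty acids, rose in 10 of 10 obese hearts to 47.8 ± 12.8 against 3.27 ± 0.977 CPM (n = 10 and 10). Pdk4 (ENSRNOG00000009565), which holds back glucose oxidation, rose to 486 ± 150.4 against 153 ± 50.5 CPM, and Nppa (ENSRNOG00000008176), the atrial natriuretic peptide, to 1173 ± 631 against 483 ± 206 CPM. The fast myosin Myh6 fell to 6639 ± 1491 against 10980 ± 2242 CPM, while Myh7 and Nppb were not called, at 0.57 ± 0.18 and 0.33 ± 0.18 with edgeR adjusted p = 0.06 and 0.355.

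Among the highest called genes were Angptl4 at 3.86 ± 0.17, Pik3c2g at 3.74 ± 0.24, Alox15 at 3.49 ± 0.22, Lgals5 at 2.06 ± 0.21 and Postn at 2.04 ± 0.24, and the lowest Card9 at -4.50 ± 0.35, Pnpla3 at -1.82 ± 0.28, Hk2 at -1.57 ± 0.38, Bdh1 at -1.47 ± 0.23, Gcat at -1.47 ± 0.20 and Cxcl11 at -1.39 ± 0.14. Of the fatty acid oxidation genes 10 of 20 rose (12 adjusted over the list alone), with Decr1 at 1.24 and Ech1 at 0.78. Their median was 0.37 (camera adjusted p = 3.96e-16, adjusted p = 0.0662 with an estimated correlation). Among PPARα targets 9 of 14 rose (10), with Ucp3 at 1.23. Their median was 0.79 (camera adjusted p = 3.06e-15, adjusted p = 0.00209 with an estimated correlation). Single called genes that rose were Tnni1 at 1.19 and Ccn2 at 0.89, of cardiac stress, Nppa, of the atrium, Mrc1 at 0.65, of myeloid cells, Cidea at 0.59, of fat cells, Mthfd2 at 0.82, of the ATF4 response, and Ahsp at 2.84, of red cells. In these lists and matrix the higher and lower genes were 4 and 0 of 14 (7 and 0) for cardiac stress, 2 and 0 of 9 for atrial, 5 and 0 of 32 (6 and 0) for extracellular matrix, 5 and 0 of 21 (8 and 0) for myeloid, 4 and 0 of 7 (5 and 0) for adipocyte, 4 and 0 of 5 (4 and 1) for erythroid and 3 and 0 of 17 (7 and 0) for ATF4 stress (camera adjusted p = 1.34e-07 to 0.0155, adjusted p = 0.0477 to 0.508 with an estimated correlation). The estimated value stayed under 0.05 for erythroid and adipocyte genes, at 0.0477 for each. In lipogenesis 3 of 14 fell and 1 rose (4 and 2), with Scd2 at -0.84 (camera adjusted p = 0.0155, adjusted p = 0.106 with an estimated correlation). Branched-chain amino acid genes included Bcat2 at -0.65 and Acadsb at -0.54, and 3 of 26 fell (5), without passing (camera adjusted p = 0.0611). Ppm1k stood at -0.62 ± 0.29 with edgeR adjusted p = 0.267. The other lists did not pass (camera adjusted p = 0.0536 to 0.567), cardiomyocyte genes among them, where 1 of 19 fell. Median, mean and test differed in sign for glucose response (median 0.25, mean -0.15, test up), NRF2 target (median -0.08, mean 0.03, test up) and immediate-early (median -0.04, mean 0.10, test up). By edgeR 680 of 12694 genes were called, 422 higher and 258 lower. The count was 647 (387 higher and 260 lower) without vehicle replicate 10, and 49 in plate 2. Dbt, at -0.54 ± 0.15 before, lost its call without that replicate at -0.50 ± 0.15 (adjusted p = 0.0673) by edgeR.

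BT2 against vehicle in obese hearts had few called genes and a shift of matrix genes. Col3a1 (ENSRNOG00000003357), the collagen of interstitial fibrosis, fell to 155 ± 41.3 against 247 ± 39.2 CPM (n = 10 and 10) and was lower in 10 of 10 libraries. The called genes with a symbol were Gstz1 at 0.59 ± 0.11, Slc38a3 at 0.49 ± 0.09, Col3a1 at -0.69 ± 0.13, Mfap4 at -0.53 ± 0.09 and Cd248 at -0.47 ± 0.09, each with edgeR adjusted p = 0.0442. All 7 calls (3 higher and 4 lower of 12545) ended without vehicle replicate 10, where edgeR called 0 genes, with 996 at an unadjusted p under 0.05 against 986 before. The 5 genes then stood at 0.58 ± 0.11, 0.49 ± 0.10, -0.68 ± 0.13, -0.49 ± 0.09 and -0.43 ± 0.09 (adjusted p = 0.0734 for each). DESeq2 called 95 genes and a fit without the plate term 0. In the matrix list 1 of 32 fell (17 adjusted over the list alone). Their median was -0.36 (camera adjusted p = 2.97e-23, adjusted p = 0.0306 with an estimated correlation). Other lists shifted with no gene called over all genes. In those shifted down the higher and lower genes adjusted over the list alone were 0 and 3 of 14 for PPARα target, 0 and 3 of 17 for ATF4 stress, 0 and 9 of 21 for myeloid, 0 and 2 of 26 for interferon response, 0 and 2 of 19 for cell cycle, 0 and 1 of 12 for immediate-early, 0 and 4 of 6 for erythroid, 0 and 1 of 14 for cardiac stress and 0 and 0 of 9 for atrial (camera adjusted p = 1.25e-10 to 0.0473, adjusted p = 0.101 to 0.418 with an estimated correlation), and in those shifted up 1 and 0 of 26 for branched-chain amino acid, 0 and 0 of 18 for cholesterol synthesis, 0 and 0 of 17 for clock and 0 and 0 of 19 for cardiomyocyte (camera adjusted p = 0.00198 to 0.0409, adjusted p = 0.118 to 0.448 with an estimated correlation). The remaining lists did not pass (camera adjusted p = 0.0797 to 0.837). Bcat2, Ppm1k and Nppa stood at 0.36 ± 0.09, 0.19 ± 0.29 and -0.67 ± 0.25, with edgeR adjusted p = 0.126, 0.97 and 0.439.

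Empagliflozin in the heart raised Bcat2 (ENSRNOG00000020956), the first enzyme of branched-chain amino acid breakdown, to 106 ± 15.0 against 75.2 ± 8.81 CPM (n = 10 and 10), in 10 of 10 libraries. Other called genes included Gcat at 0.70 ± 0.14, Gstz1 at 0.54 ± 0.08, Hhatl at 0.41 ± 0.08, Acy1 at 0.40 ± 0.07, Eno3 at 0.38 ± 0.06, Slc2a4 at 0.37 ± 0.07, Gstk1 at 0.32 ± 0.06, Pccb at 0.28 ± 0.05, Qdpr at 0.28 ± 0.05, Ucp3 at -0.62 ± 0.12 and Sfrp2, under 5 CPM, at -1.23 ± 0.24. By edgeR 13 of 12167 genes were called (10 higher and 3 lower), 69 by DESeq2 and 2 (0 higher and 2 lower) without libraries high in Myl7 or Myh4, where Bcat2, at 0.49 ± 0.08 before, stood at 0.48 ± 0.09 (adjusted p = 0.085) and Gstz1 at 0.44 ± 0.08 (adjusted p = 0.0806) by edgeR. Chance was not excluded for the count of 13. Plate 1 alone gave 1236, plate 2 alone 0 and the replicate number as a block 4. In branched-chain amino acid catabolism 2 of 26 rose (3 adjusted over the list alone). Their median was 0.13 (camera adjusted p = 2.36e-08, adjusted p = 0.222 with an estimated correlation). Among PPARα targets 2 of 14 fell (4) (camera adjusted p = 1.72e-06, adjusted p = 0.146 with an estimated correlation). Other lists shifted with no gene called over all genes. In those shifted up the higher and lower genes adjusted over the list alone were 0 and 0 of 26 for oxidative phosphorylation, 0 and 0 of 25 for interferon response, 5 and 1 of 16 for clock and 3 and 0 of 19 for cardiomyocyte (camera adjusted p = 4.57e-07 to 0.00417, adjusted p = 0.0759 to 0.552 with an estimated correlation), and in those shifted down 0 and 3 of 5 for glucose response, 0 and 1 of 18 for cholesterol synthesis, 0 and 0 of 32 for extracellular matrix and 0 and 0 of 16 for cell cycle (camera adjusted p = 1.74e-09 to 0.0174, adjusted p = 0.146 to 0.203 with an estimated correlation). The remaining lists did not pass (camera adjusted p = 0.115 to 0.925). Pdk4 and Nppa were not called, at -0.58 ± 0.14 and -0.35 ± 0.58 with edgeR adjusted p = 0.137 and 0.908.

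Combination treatment lowered Angptl4 in the heart to 10.8 ± 7.89 against 38.0 ± 13.8 CPM (n = 10 and 10) and Pdk4 to 228 ± 55.9 against 472 ± 139 CPM, each in 10 of 10 libraries. Cyp26b1 (ENSRNOG00000015076), which breaks down retinoic acid, rose to 12.7 ± 4.77 against 4.30 ± 1.12 CPM, and Bcat2 to 116 ± 20.7 against 75.4 ± 8.87 CPM. Highest among called genes were Tnnc2 at 4.70 ± 0.99, Mylpf at 4.37 ± 1.06, Actn3 at 3.87 ± 0.96, Myh4 at 3.70 ± 0.98, Spp1 at 2.41 ± 0.64 and Cyp26b1 at 1.56 ± 0.17, of which the first 4 belong to skeletal muscle and stood highest in combination replicate 9. Without libraries high in Myl7 or Myh4, Tnnc2 moved to 1.87 ± 0.37 (adjusted p = 0.0246), and Mylpf, Actn3, Myh4 and Spp1 lost their calls at 0.99 ± 0.33 (adjusted p = 0.186), 1.3 ± 0.34 (adjusted p = 0.0927), 1.32 ± 0.35 (adjusted p = 0.0952) and 1.46 ± 0.39 (adjusted p = 0.0939) by edgeR. Among the lowest were Alox15 at -2.03 ± 0.27, Angptl4 at -1.99 ± 0.24, Pik3c2g at -1.52 ± 0.24, Pdk4 at -1.03 ± 0.14 and Slc17a7 at -0.99 ± 0.24. Of the branched-chain amino acid genes 6 of 26 rose (16 adjusted over the list alone), with Pccb at 0.34 and Bcat2 at 0.62 (camera adjusted p = 5.9e-09, adjusted p = 0.263 with an estimated correlation). For oxidative phosphorylation 10 of 26 rose (15), with Atp5po at 0.32 (camera adjusted p = 4.3e-12, adjusted p = 0.211 with an estimated correlation). Cardiomyocyte genes had Tnni3 at 0.44, and 6 of 19 rose (8) (camera adjusted p = 1.67e-05, adjusted p = 0.211 with an estimated correlation). Among PPARα targets 4 of 14 fell (7) (camera adjusted p = 1.64e-06, adjusted p = 0.137 with an estimated correlation). In the matrix list 4 of 32 fell (6), with Loxl2 at -0.62 and Ccn2 at -0.65 (camera adjusted p = 8.13e-07, adjusted p = 0.44 with an estimated correlation). Clock genes had Per3 at 0.98 against Arntl at -0.71, and 6 of 16 rose and 2 fell (9 and 3) (camera adjusted p = 0.0371, adjusted p = 0.137 with an estimated correlation). Glucose response genes such as Txnip at -0.82 and interferon genes shifted down, with 0 and 2 of 6 (2 and 3) for glucose response and 0 and 1 of 25 (1 and 4) for interferon response (camera adjusted p = 0.0228 to 0.0267, adjusted p = 0.137 to 0.57 with an estimated correlation). The remaining lists did not pass (camera adjusted p = 0.0573 to 0.903). Nppa was not called, at -0.88 ± 0.48 with edgeR adjusted p = 0.333. By edgeR 622 of 12117 genes were called, 434 higher and 188 lower, and 111 (75 higher and 36 lower) without libraries high in Myl7 or Myh4. The count was 141 without the plate term, and 77 and 6 within each plate.

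Combination against empagliflozin alone in the heart left 3 called genes of 12049 by edgeR (980 at an unadjusted p under 0.05 and 65 by DESeq2), namely Cyp26b1 at 1.31 ± 0.19, Ptgr1 at 0.47 ± 0.07 and Gstz1 at 0.52 ± 0.09. Gstz1 lost its call without libraries high in Myl7 or Myh4, at 0.57 ± 0.10 (adjusted p = 0.0641). With the replicate number as a block edgeR called 0 (843 unadjusted). No list had a gene called over all genes. In those shifted up the higher and lower genes adjusted over the list alone were 0 and 0 of 26 for branched-chain amino acid, 1 and 0 of 26 for oxidative phosphorylation and 0 and 0 of 11 for immediate-early (camera adjusted p = 2.52e-05 to 0.0395, adjusted p = 0.382 to 0.579 with an estimated correlation), and in those shifted down 0 and 2 of 14 for PPARα target, 0 and 2 of 6 for glucose response and 0 and 7 of 25 for interferon response (camera adjusted p = 4.46e-10 to 0.0333, adjusted p = 0.281 to 0.306 with an estimated correlation). The remaining lists did not pass (camera adjusted p = 0.0759 to 0.617). BT2's effect with minus without empagliflozin had 0 called genes of 12992 by edgeR, 516 at an unadjusted p under 0.05 and 1 by DESeq2.

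Obese vehicle hearts of study B were also set against those of study A, without drug. Per3, of the circadian clock, fell to 9.22 ± 3.27 against 23.0 ± 9.45 CPM (n = 10 and 10) and Arntl rose to 31.0 ± 6.33 against 16.6 ± 5.80 CPM, each in 10 of 10 libraries. Highest were Bmp10 at 3.89, Sbk3 at 2.89, Sbk2 at 2.63, Atp1b4 at 2.43, Rxfp1 at 1.90 and Epha4 at 1.37. Bmp10 is made in atria. Without libraries high in Myl7 or Myh4 all 6 lost their calls at 0.09 to 0.66 (edgeR adjusted p = 0.529 to 0.935). The lowest were Myh4 at -1.88, Mcc at -1.72, Dbp at -1.5, Nfib at -1.48, Prkaa2 at -1.47 and Zyg11b at -1.34. Without those libraries Myh4, Postn and Ahsp lost their calls at -1.62, -0.51 and -0.47 (edgeR adjusted p = 0.064, 0.0669 and 0.27). Among immediate-early genes 10 of 12 fell (10 adjusted over the list alone), with Zfp36 at -0.98 and Ier2 at -0.78. Their median was -0.51 (camera adjusted p = 4.01e-09, adjusted p = 0.129 with an estimated correlation). Clock genes went both ways, as 7 of 17 fell and 3 rose, with Per1 at -0.92 (camera adjusted p = 0.345). The matrix gene Postn at -0.74, the interferon gene Psmb9 at -0.80 and the red cell gene Ahsp at -0.79 fell. In their lists and the myeloid one the higher and lower genes were 0 and 5 of 32 (0 and 8) for extracellular matrix, 0 and 6 of 26 for interferon response, 0 and 4 of 6 for erythroid and 0 and 0 of 21 for myeloid (camera adjusted p = 0.00278 to 0.046, adjusted p = 0.781 to 0.781 with an estimated correlation). The other lists did not pass (camera adjusted p = 0.0944 to 0.945). Median, mean and test differed in sign for fatty acid oxidation (median 0.05, mean -0.01, test down), PPARα target (median 0.04, mean -0.02, test up), NRF2 target (median 0.04, mean -0.01, test up) and cardiomyocyte (median -0.01, mean 0.02, test down). By edgeR 1459 of 12433 genes were called, 428 higher and 1031 lower, but 634 higher and 857 lower with DESeq2 size factors. The count was 877 (274 higher and 603 lower) without libraries high in Myl7 or Myh4, 1345 without study A vehicle replicate 10, 95 without the plate term, and 916 and 0 within each plate.

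Across genes called between obese and lean hearts, treatment effects correlated negatively with the obesity effect, more weakly over all genes. The combination gave r = -0.472 (-0.442 and -0.443 with the effects taken from different plates), and 43 of the genes raised by obesity fell, against 6.42 for independent lists. Empagliflozin gave r = -0.501 (-0.493 and -0.338 from different plates). BT2, which shares its vehicle with the obesity contrast, gave r = -0.683 (-0.562 and -0.535 from different plates). There simulated null data with the same shared vehicle gave r = -0.473, and the covariance was -0.151 against -0.0117 simulated. Empagliflozin and combination effects, over all genes measured in both, gave r = 0.564 (0.220 and 0.10 from different plates). Here simulated null data gave r = 0.506 (covariance 0.0198 against 0.0165 simulated).

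**Figure D2:**
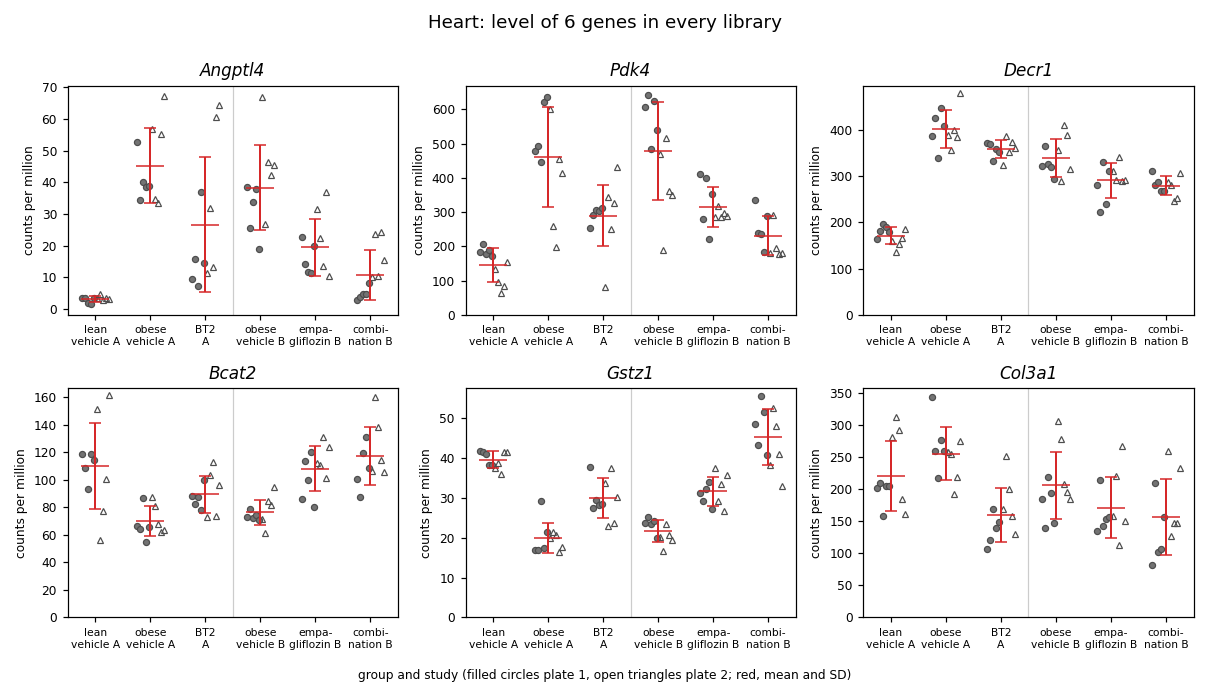
Levels in CPM of 6 heart genes in every library, drawn as for kidney. Angptl4 and Pdk4 were higher in obese vehicle hearts than in lean ones, and lower with the combination.

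Effects in heart minus effects in kidney were tested directly. For obesity 2097 of 14926 genes differed by edgeR, 957 higher and 1140 lower in heart, such as Decr1, of fatty acid oxidation, at 1.28 ± 0.11 (edgeR adjusted p = 4.8e-10) and the matrix receptor Cd44 at -1.60 ± 0.17. Without the libraries with other-tissue transcripts the split was 765 higher and 1754 lower, with DESeq2 size factors 1092 and 1078, and plate 2 alone gave 86. For the combination 2381 of 14692 genes differed (1219 higher and 1162 lower, and 1145 without other-tissue libraries), with the lipid genes Scd2 at -2.88 ± 0.17 and Ehhadh at -2.49 ± 0.20. BT2 alone gave 79 of 14975 (35 higher and 44 lower, and 114 without BT2 replicate 2 of kidney). Empagliflozin gave 206 of 14732 (162 higher and 44 lower), with Ace at -0.98 ± 0.14 (edgeR adjusted p = 0.00013) and 92 genes without other-tissue libraries.

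**Figure D3:**
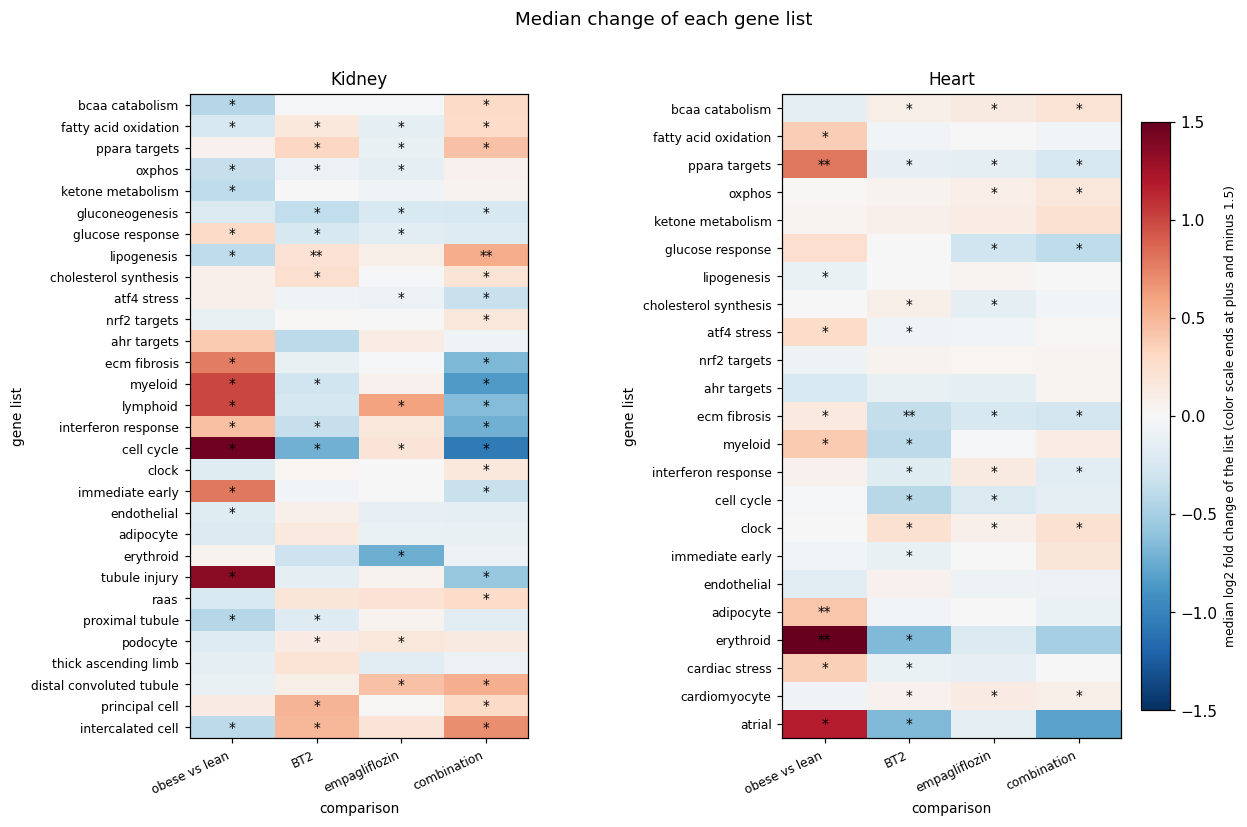
Median log2 fold change of each gene list (color) in 4 comparisons per organ, with 1 star where camera passed and 2 where it also passed with an estimated correlation. In kidney, medians of injury, matrix and immune lists were above 0 in obesity and below 0 with the combination.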

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

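The ratio of fast to cardiac myosin and the count of atrial transcripts were tests chosen only after the result was seen. Of 162 groups of values 18 had a sample far from the others, where chance sets apart about 1 in 20 groups. Values are given against the nearest library of the same group, with counts in units of 1000000 (M).

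Kidney lean replicate 8 stood apart with 54.9 against 28.1 M counts, Bckdk at 189 against 154 CPM, Ppm1k at 56.2 against 92.6 CPM, Slc5a1 at 15.7 against 24.3 CPM, Havcr1 at 165 against 22.5 CPM and Lcn2 at 18.4 against 4.14 CPM. Its muscle transcripts were not those of heart alone, since the ratio of Myh4 to Myh6 was 7.06 and at most 0.152 in any heart library. Over 113 genes at least 4 times higher in obese kidneys it lay a median of 55.8% of the way from the other lean libraries to the obese mean (at most 4.59% in another lean library and 65.5% to 130% in the obese libraries). Over 145 genes at least 2 times lower in obese kidneys it lay 94.3% of the way (at most 13.3% in another lean library and 88.6% to 107% in the obese libraries). RNA or reads of an obese kidney in this library and an obese library labelled lean both stay open as candidate explanations, and no biological explanation was tested.

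Nppa stood apart in heart at 8430 against 3900 CPM in study B vehicle replicate 7 and at 8050 against 2950 CPM in empagliflozin replicate 6. In the 9 libraries high in Myl7, 8 of them of study B, Nppa, Myl4, Sln and Bmp10 were above 2 times the heart median in 35 of 36 pairs of gene and library, so atrial tissue in the pieces may explain the values. Stress of the ventricle is argued against, as 13 cardiac stress genes without atrial ones had a median ratio of 1.06 to the heart median in these libraries.

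Other kidney samples far from the others were obese vehicle A replicate 6 with Havcr1 at 519 against 354 CPM and BT2 replicate 2 with 0.0228 against 8.28 M counts. Empagliflozin replicates 5 and 6 held Slc5a2 at 254 against 146 CPM and Slc5a1 at 37.3 against 22.8 CPM. Combination replicate 10 had 32.0 against 19.5% mitochondrial counts and replicate 3 Ppm1k at 96.1 against 63.0 CPM. In heart, lean replicate 7 held Nppa at 907 against 608 CPM, BT2 replicates 7 and 6 Myh7 at 21700 against 15000 CPM and Pdk4 at 81.1 against 250 CPM, and study B vehicle replicate 8 had 21.8 against 14.2 M counts.

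Effects that differed between backgrounds or organs came from edgeR tests of the difference itself. The BT2 effect with minus without empagliflozin was called in kidney for 1167 genes, a count for which chance was not excluded, among them Bckdhb at 0.34 (adjusted p = 0.0493), Bckdk at 0.27 (adjusted p = 0.0336), Dbt at 0.43 (adjusted p = 0.0225), Lcn2 at -0.99 (adjusted p = 0.00959), Myh6 at 6.40 (adjusted p = 0.00788), Ppm1k at 1.36 (adjusted p = 0.00054) and Slc5a2 at -0.96 (adjusted p = 0.0478). Without other-tissue libraries Myh6, a heart gene, stood at 1.53 ± 1.38 (adjusted p = 0.514), and Bckdhb, Bckdk and Slc5a2 at 0.31 ± 0.12 (adjusted p = 0.0988), 0.24 ± 0.09 (adjusted p = 0.0808) and -0.79 ± 0.34 (adjusted p = 0.131). Heart minus kidney differed for 2097 genes for obesity, with Havcr1 at -5.73 (adjusted p = 0.00219), Lcn2 at -3.07 (adjusted p = 2.1e-06), Nppa at 5.00 (adjusted p = 0.041) and Nppb at 4.53 (adjusted p = 0.0344). Kidney lean replicate 8 held Nppa at 201 against a median of 0.105 CPM, and without other-tissue libraries Nppa, Nppb, Havcr1 and Lcn2 stood at 1.0 ± 0.85 (adjusted p = 0.486), -0.28 ± 0.80 (adjusted p = 0.875), -7.01 ± 0.97 (adjusted p = 1.66e-06) and -3.89 ± 0.25 (adjusted p = 9.38e-14). Heart lean replicate 8, not left out there, held Havcr1 at 7.75 against a median of 0.177 CPM. For BT2 the count was 79 and for empagliflozin 206, with Bckdha at 0.60 (adjusted p = 0.018), or 0.57 ± 0.14 (adjusted p = 0.0525) without such libraries. For the combination it was 2381, with Havcr1 at 1.98 (adjusted p = 0.0156), Lcn2 at 0.76 (adjusted p = 0.0256), Myh6 at -4.70 (adjusted p = 0.00319), Nppa at -4.48 (adjusted p = 0.0307), Nppb at -4.07 (adjusted p = 0.0126), Pdk4 at -0.97 (adjusted p = 0.000413) and Ppm1k at -1.62 (adjusted p = 2.62e-05). Combination replicate 7 of kidney held Myh6 at 242 against a median of 0.913 CPM, and without such libraries Myh6, Nppa and Nppb stood at -0.63 ± 0.37 (adjusted p = 0.313), 0.24 ± 2.22 (adjusted p = 0.994) and -0.19 ± 0.84 (adjusted p = 0.952), and Havcr1 and Lcn2 at 1.21 ± 0.78 (adjusted p = 0.382) and 0.69 ± 0.33 (adjusted p = 0.216).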

How the results depend on the processing

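Only the settings without certain libraries were chosen after the results were seen, namely without the 3 kidney libraries absent from the authors' tables, without libraries with another tissue's transcripts, without heart study A vehicle replicate 10 and without kidney empagliflozin replicate 1. Of 223 alternative counts of called genes 139 stayed within 1.5 times the reported one. Of 3865 values of named genes 3432 kept their side of the threshold, though uncalled ones could change sign. The call was lost in 420 and gained in 13, and 0 called ones reversed. Of 1200 list tests 1038 stayed on their side, 146 lost the call, 135 of these with an estimated correlation, and 16 gained one. With DESeq2 size factors in place of TMM 18 of 18 counts stayed within 1.5 times. Where counts went to 0 below, the number at an unadjusted p under 0.05 by edgeR stands beside it. Here adding BT2 stands for combination against empagliflozin, and the interaction for the BT2 effect with minus without empagliflozin. The cause was not tested unless stated.

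The DESeq2 Wald test moved the counts to 1357 for BT2 and 623 for empagliflozin in kidney. In heart they were 95 for BT2, 69 for empagliflozin, 65 for adding BT2 and 1 for the interaction. Heart minus kidney gave 225 for BT2 and 538 for empagliflozin. Without the plate term the counts became 503 for BT2 and 25 for empagliflozin in kidney. Heart counts were 372 for obesity, 0 for BT2 (702 unadjusted), 4 for empagliflozin, 141 for the combination and 95 for the vehicle groups. The difference of heart and kidney gave 37 for BT2, 7 for empagliflozin and 1237 for the combination. With the replicate number as a block in place of the plate they became 290 for BT2 and 33 for empagliflozin in kidney. Those of heart were 0 for BT2 (730 unadjusted), 4 for empagliflozin, 258 for the combination and 0 for adding BT2 (843 unadjusted). In heart minus kidney they were 32 for BT2 and 15 for empagliflozin. Libraries of the same replicate number had a median r of residuals from -0.111 to 0.122 across the comparisons, highest for empagliflozin in heart, where 6 of 10 pairs exceeded 0.1. All 6 groups of an organ in one fit gave 1248 for BT2 in kidney and 1068 for obesity, 12 for BT2 and 21 for adding BT2 in heart.

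Fewer samples per plate lower the counts by construction, but the plates also differed from each other. Plate 1 alone gave 113 for BT2, 2 for empagliflozin, 2480 for the combination and 122 for the interaction in kidney. In heart they were 4 for BT2, 1236 for empagliflozin, 77 for the combination, 25 for adding BT2, 916 for the vehicle groups and 1 for the interaction. Heart minus kidney gave 12 for BT2, 1255 for empagliflozin and 844 for the combination. Plate 2 alone gave 976 for obesity, 70 for BT2, 21 for empagliflozin, 1752 for the combination, 1133 for adding BT2, 5397 for the vehicle groups and 8 for the interaction in kidney. Heart counts were 49 for obesity, 0 for BT2 (366 unadjusted), 0 for empagliflozin (1078 unadjusted), 6 for the combination, 0 for adding BT2 (1340 unadjusted) and 0 for the vehicle groups (1478 unadjusted). The difference of heart and kidney gave 86 for obesity, 4 for BT2, 1 for empagliflozin and 396 for the combination.

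With the original run alone, which lowers depth, the counts were 472 for BT2, 75 for empagliflozin and 679 for the interaction in kidney. Those of heart were 7 for empagliflozin, 276 for the combination and 1 for the interaction. In heart minus kidney they were 43 for BT2 and 25 for empagliflozin. The repeat run in place of the original gave 0 for BT2 (930 unadjusted) and 5 for empagliflozin in heart. A term for a repeat run gave 189 for BT2 and 389 for empagliflozin in kidney and 40 for BT2 and 346 for empagliflozin in heart minus kidney. Without a low-count filter, so with more genes tested, the count was 115 for empagliflozin in heart minus kidney. Without the 3 libraries absent from the authors' tables it was 92 for empagliflozin in kidney. Without libraries with another tissue's transcripts, so also with fewer libraries, the counts were 2950 for adding BT2 in kidney. In heart they were 0 for BT2 (897 unadjusted), 2 for empagliflozin, 111 for the combination and 877 for the vehicle groups. Heart minus kidney gave 92 for empagliflozin and 1145 for the combination. Without vehicle replicate 10 the count was 0 for BT2 (996 unadjusted) in heart.

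Of 26 alternative correlations of effects 13 changed by less than their spread. With the first effect from plate 1 and the second from plate 2, r reversed to -0.321 for empagliflozin against obesity in kidney and -0.0771 for empagliflozin against the combination in kidney, and moved to -0.622 for the combination against obesity in kidney, -0.562 for BT2 against obesity in heart and 0.220 for empagliflozin against the combination in heart. With the plates the other way round r against obesity was -0.597 for the combination in kidney. In heart it was -0.535 for BT2 and -0.338 for empagliflozin, and 0.10 for empagliflozin against the combination. Over all tested genes r against obesity was -0.538 for the combination in kidney. In heart it was -0.386 for BT2, -0.110 for empagliflozin and -0.0908 for the combination.

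Libraries of each comparison were regrouped 40 times at random, the real grouping included. In 15 comparisons only the real one gave as many genes, a share of 1 in 40, the lowest possible and not corrected. The real counts and the highest of the other groupings were 4559 and 1393 for obesity, 812 and 0 for BT2, 149 and 0 for empagliflozin, 4510 and 492 for the combination, 4442 and 0 for adding BT2 and 9442 and 6881 for the vehicle groups in kidney. In heart they were 680 and 5 for obesity, 7 and 0 for BT2, 622 and 1 for the combination, 3 and 0 for adding BT2 and 1459 and 8 for the vehicle groups. In heart minus kidney they were 2097 and 203 for obesity, 79 and 1 for BT2, 206 and 1 for empagliflozin and 2381 and 11 for the combination. For the interaction in kidney chance was not excluded, as 2 of 40 groupings gave as many genes as the 1167 found, with a highest of 1654, a share at the threshold of 0.05, and with 10 more regroupings it was under 0.05. For empagliflozin in heart chance was not excluded, as 3 of 40 groupings gave as many genes as the 13 found, with a highest of 52. Why a random grouping gave so many was not traced. For the interaction in heart edgeR called 0 genes (516 unadjusted, 1 by DESeq2), so regrouping could not test it.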

Other observations

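Clock genes were compared only after the result was seen. Kidney vehicle groups of the 2 studies differed widely. Depth is argued against, since 8906 genes were still called after thinning 19 libraries to 8002855 counts each. More medulla and less cortex in study B could not be decided. Its 5 measured marker genes had a median log2 fold change of 0.88, but 3 were called higher, among them Slc6a12 at 0.92 ± 0.16 and Akr1b1 at 0.88 ± 0.34, and 1 lower, Slc12a2 at -0.25 ± 0.11. Sampling at another time of day may underlie part of the difference, as 8 of the 10 clock genes called between the vehicle hearts were called with the same sign in kidney and 0 with the opposite one, for example Per3 at -1.32 in heart and -1.01 in kidney. Since 9442 of 14434 kidney genes were called, shared signs are common there. The combination shifted clock lists too, and sampling time was not tested for it.

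Empagliflozin raised Cyp24a1 and Vdr and lowered Slc34a3 in the kidney. More FGF23 or active vitamin D could each give part of this. Each predicted a lower Cyp27b1, which cannot separate them. Cyp27b1, which makes active vitamin D, stood at -1.07 ± 0.26 (edgeR adjusted p = 0.0472). Without vehicle replicate 8 it was at -1.07 ± 0.26 (adjusted p = 0.0593, fewer samples), and Slc34a3 lost its call too. Of 5 vitamin D targets of the distal tubule edgeR called 0 higher and 0 lower, with Trpv5 at 0.84 ± 0.31, Calb1 at 0.49 ± 0.32 and Atp2b1 at 0.25 ± 0.07, so that test decided nothing.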
